A study of Oryza sativa with 16 samples.

How the data were processed

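RNA from the shoots and roots of rice seedlings (Oryza sativa, cultivar Nipponbare) was measured on 2-colour Agilent oligonucleotide arrays. Per the labels' protocols, germinated rice was treated in test tubes for 2 weeks at 28 °C with 2-azahypoxanthine (AHX) or 2-aza-8-oxohypoxanthine (AOH), each at a dose the labels write as 50 mM or 200 mM, and 200 ng of total RNA was labelled per channel. The labels' dose unit is kept here, but such doses are very high for seedlings and the unit may stand for µM, so the absolute doses are uncertain. There are 8 groups (2 organs, 2 compounds and 2 doses) of 2 arrays each, and every array carries treated RNA in one channel and RNA of untreated seedlings in the other. No array compares untreated with untreated RNA, so the spread between untreated seedlings is not in any test.

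Per the file headers and the submitters' processing notes, the slides were read with Agilent Feature Extraction 10.7.3.1 on array design 015241, whose probe positions refer to rice genome build 5 (IRGSP). The deposited scanner files give each spot's mean brightness and local background as intensity on a linear scale for Cy3 and Cy5, and, per the file headers, processed intensity values from which Feature Extraction had subtracted background and removed dye bias by linear and lowess scaling. Per the file headers, the deposited LogRatio is the log10 of Cy5 over Cy3 processed signal. The deposited value table was set against each array's scanner values by spot number: it equalled the log10 LogRatio of the same array within 0.005, so its scale is log10, it is not turned to treated over control, and no centring beyond Feature Extraction's was found. Its 16 column medians lay between -0.0013 and 0.

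Median spot brightness per array ran from 258 to 484 in Cy3 and from 536 to 886 in Cy5, against median local backgrounds of 17 to 29.5 and 35 to 39.5. Between 80% and 83% of probe spots were well above background in Cy3 and between 78.1% and 84% in Cy5. No spot was saturated, and 48 to 103 spots per array carried the scanner's outlier mark and were removed. The number of arrays limits the precision.

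Mean and background signals were corrected with normexp (offset 50) and normalized within each array by loess with control spots at weight 0, in limma 3.58.1 under R 4.3.3 with the package data.table (version 1.17.8). Loess sets the typical ratio of each array to 0, so a change shared by most genes would not be seen. The offset draws ratios of dim spots toward 0, so folds are smaller than those from the scanner's processed signals. Spots of one probe were averaged. Of 42477 probes, 34955 were tied to 1 rice locus by the files' annotation columns, 1020 to several, 6029 only through the probe name and 473 to none. The reference table of gene symbols lists hardly any locus numbers of this kind, so names and descriptions are those of the array files, with textbook names added where they are well known. Each of 29214 genes was represented by its probe with the highest mean intensity. A gene was tested in an organ when its probe was well above background in either channel on at least 2 of the organ's 8 arrays. Where a probe was not well above background in the treated or control channel on either array of a group, its fold is given as a bound: the brighter channel's mean over both arrays against, per array, the higher of the lowest signal among probes well above background and the dim probe's own, after loess and Aquantile scaling.

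The labels hold a pair of conflicts. On 4 arrays the title, description and source name say 200 mM AOH while the treatment characteristic says 200 mM AHX; they were grouped by title. The labels also give treated RNA the dye Cy5 on all arrays but turn the order of the channels in replicate 2. The rule for this case was set before the data were examined. Cy5 over Cy3 ratios of the replicates of a group correlated at -0.957 to -0.832 across probes (median -0.914 over 8 pairs). After subtracting the mean of the arrays of the same organ and replicate number the correlations were -0.976 to -0.936 (median -0.965). By the rule, replicate 2 was therefore taken as dye-swapped, against its labelled dyes: treated over control is Cy5 over Cy3 in replicate 1 and Cy3 over Cy5 in replicate 2. The direction of all changes rests on the labelled dyes of replicate 1 and is called likely.

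All 16 arrays entered one limma fit with 8 group coefficients and 1 dye term per organ, which is also the replicate block. It leaves 6 residual degrees of freedom (10.42 with the prior). Pairing was checked: deviations of same-numbered arrays from their group means correlated at 0.85 to 0.91 in shoots and 0.77 to 0.9 in roots over 6 pairs of groups each. In shoots same-numbered arrays share the dye orientation, and in roots also the slide, so these cannot be told apart from a shared batch of seedlings. Contrasts were each treatment against control, 200 against 50 mM, AOH against AHX at matched dose, and root against shoot at 200 mM. Benjamini-Hochberg adjustment was made over the genes tested in each contrast, with a threshold of 0.05. Every adjusted p printed comes from limma. Errors given as SE are moderated standard errors over 2 arrays per group, and intervals are 95%. The labels do not say whether replicates came from separate seedlings or from a dye swap of the same extracts, nor whether control RNA was shared. The p-values therefore measure only the spread between these arrays, which may be technical. Because most genes past the threshold changed by less than 2-fold, changes of at least 2-fold (1 on the log2 scale) are counted beside them.

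The 29 gene lists, defined by description patterns and locus numbers before the data were examined, cover glutathione S-transferases, Bowman-Birk protease inhibitors, aquaporins, UDP-glycosyltransferases, cytochromes P450, ABC and MATE transporters, purine metabolism and transport, nitrogen uptake and assimilation, phosphate starvation, iron deficiency and phytosiderophores, cytokinin response and breakdown, auxin response, late embryogenesis and abscisic acid response, jasmonate synthesis and response, ethylene synthesis and response, pathogenesis-related proteins, diterpenoid phytoalexin synthesis, phenylpropanoid and flavonoid synthesis, class III peroxidases, antioxidant enzymes, heat shock proteins and chaperones, photosynthesis, cytosolic ribosomal proteins, histones and cell cycle, cell wall remodelling, WRKY transcription factors, NAC transcription factors, sugar metabolism and transport, and seed storage proteins. Each list was tested against the other genes with limma's camera (preset correlation 0.01, and again with the correlation estimated), adjusted over the lists of a comparison.

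Genes were named by a rule set before the data were examined. Per organ and compound it takes the 6 largest increases and 6 largest decreases at 200 mM, the 4 and 4 largest at 50 mM, and up to 3 members of each list, among genes past the threshold with the same sign on both arrays; for each other contrast it takes the 4 and 4 largest. How to read "with a name or description" in that rule was decided after the genes with the largest changes had been seen: of 26212 genes in the fit, 16280 were open to naming, 9312 were left out for a description without a name or function, and 620 because their probe was tied to several loci. Clock genes and the 12 genes plotted by group were chosen after their values were seen.

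The alternatives tried were no background correction, the scanner's processed signals, the value table, an added Aquantile step, median centring in place of loess, no filter on dim probes, a stricter filter, no replicate block, the other orientation of replicate 2, a fit on the arrays of one organ, the mean of all probes of a gene, and each array left out. A dye term per slide in shoots and a fit without the 4 arrays of conflicting labels were added after the data were seen. Data were simulated for root AOH 200 mM with 200 of 25090 genes changed (real calls: 21082). The fit called 49 of 50 genes at 0.25 (log2) and 50 of 50 at 0.5, 1 and 2 with the right sign, and 12 of 24890 unchanged genes. Wider change was untested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.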

Results

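Rice seedlings were grown with a purine analogue, and RNA of treated and untreated seedlings was hybridised together on 2-colour arrays. AHX (2-azahypoxanthine) and AOH (2-aza-8-oxohypoxanthine, which is AHX with an oxo group at carbon 8) are compounds known from fungi that form fairy rings, and both are known to promote plant growth. The design has 3 conditions: no compound, AHX and AOH, the last pair at 50 mM and 200 mM as the labels write the doses, a unit that may be an error for µM. Shoot and root were taken apart after 2 weeks, which gave 8 groups of 2 arrays. Photosynthesis genes marked the organs as labelled: their control signal stood 5.33 to 5.55 log2 units above that of all probes on the 8 shoot arrays and 2.56 to 3.05 units above it on the 8 root arrays. All values are treated over control on the log2 scale or as folds, with the SE of the limma fit over n = 2 arrays. The signs are likely, not settled. They follow the labelled dyes of replicate 1 and the labelled dyes of replicate 2 contradict them. If those of replicate 2 were the right ones every sign given here would turn and every count of higher and lower genes would change places. The arrays titled 200 mM AOH have a treatment characteristic that names AHX. In expression they lay nearer to 50 mM AOH (r across genes 0.93 in shoots and 0.9 in roots) than to 200 mM AHX (0.74 and 0.8).

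In shoots, the question was what AHX changes against untreated seedlings. With 200 mM AHX, the UDP-glucosyltransferase family gene Os09g0518200 was 5.82-fold higher (log2 2.54 ± 0.033 SE, n = 2), the wall-loosening expansin EXPA2 (Os01g0823100) 4.9-fold, the plastid RNA polymerase sigma factor SIGE (Os05g0586600) 4.82-fold and WRKY62 (Os09g0417800) 4.36-fold. An MtN3 family gene (Os01g0700100), a family that includes sugar transporters, was 4.03-fold higher. The largest decreases were those of a CRT/DRE binding factor (Os02g0677300), a cold-response regulator, at 18.6-fold (log2 -4.22 ± 0.057), a small heat shock protein (Os02g0758000) at 14.2-fold (log2 -3.83 ± 0.03) and a tify protein (Os10g0391400) at 13.8-fold (log2 -3.78 ± 0.04). The early nodulin ENOD93 gene Os06g0142300 was 12.8-fold lower, a helix-loop-helix gene (Os04g0301500) 12.7-fold and an amino acid transporter gene (Os01g0597600) 11.3-fold. At 50 mM the same WRKY62, glucosyltransferase, EXPA2 and SIGE genes led the increases, at 4.66-fold, 4.19-fold, 4.04-fold and 3.61-fold. Large decreases at 50 mM included those of chlorophyll a-b binding protein genes and the CRT/DRE binding factor. Os09g0346500 was 17.7-fold lower (log2 -4.15 ± 0.036) and the early light-induced gene Os07g0178700 13.4-fold. The adjusted p of these genes was 8.8e-14 to 9.6e-12, and the SE of the genes named for AHX in shoots was at most 0.141 (log2). Os02g0758000 fell too (log2 -3.78 at 50 mM).

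Photosynthesis genes fell as a group with AHX in shoots. At 200 mM 43 of 52 fell, 6 rose and 3 did not pass (49 changed when adjusted over the list alone), with a median of -0.56 on the log2 scale (adjusted p = 3.6e-10; adjusted p = 0.098 with an estimated correlation). At 50 mM 40 fell and 4 rose (45 changed adjusted over the list alone; adjusted p = 2.6e-11, and adjusted p = 0.11 with an estimated correlation), among them the chlorophyll a-b binding protein gene Os01g0600900 (7.2-fold lower, SE 0.036 on the log2 scale) and a light-harvesting complex I gene (Os06g0320500, 6.74-fold lower). Genes of cytosolic ribosomal proteins rose: 133 of 145 at 200 mM, 4 falling and 8 not past the threshold (137 changed adjusted over the list alone). At 50 mM 108 of 145 rose (114). Their medians were 0.34 and 0.16 (adjusted p = 5.8e-19 and 5.1e-12; adjusted p = 0.042 and 0.082 with an estimated correlation). Examples at 200 mM are the acidic protein P0 (Os11g0135400, 2.14-fold) and the 40S protein S10-1 (Os01g0962600, 1.61-fold). Jasmonate genes fell, 25 of 38 at 200 mM with 5 rising (31 changed adjusted over the list alone; adjusted p = 3e-05, and adjusted p = 0.063 with an estimated correlation). They were led by tify genes, whose proteins repress jasmonate signalling, with Os03g0181100 8.87-fold lower at 200 mM and Os03g0180800 5.87-fold lower at 50 mM. The list had fallen at 50 mM as well (22 of 38, 29 adjusted over the list alone; adjusted p = 0.0015, and adjusted p = 0.11 with an estimated correlation). Ethylene genes fell too, 28 of 39 at 200 mM (33 changed adjusted over the list alone; adjusted p = 2.7e-05, and adjusted p = 0.042 with an estimated correlation). At 50 mM 24 of 39 fell (32; adjusted p = 0.0019, and adjusted p = 0.074 with an estimated correlation).

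Glutathione S-transferases, which couple glutathione to foreign compounds, rose with AHX in shoots: 25 of 51 at 200 mM against 11 that fell (36 changed adjusted over the list alone; adjusted p = 0.031, and adjusted p = 0.19 with an estimated correlation), among them GSTF14 (Os03g0134900, 2.92-fold) and GSTF15 (Os03g0135100, 2.65-fold). At 50 mM 25 rose and 7 fell (33 changed adjusted over the list alone; adjusted p = 0.002, and adjusted p = 0.12 with an estimated correlation). UDP-glycosyltransferases rose, 63 of 129 at 200 mM against 36 that fell (99 changed adjusted over the list alone; adjusted p = 0.04, and adjusted p = 0.18 with an estimated correlation). At 50 mM 66 rose and 33 fell (99; adjusted p = 0.0095, and adjusted p = 0.11 with an estimated correlation). At 200 mM, diterpenoid phytoalexin genes rose (7 of 11, also 7 adjusted over the list alone; median 0.3, adjusted p = 0.023, and adjusted p = 0.098 with an estimated correlation). Phenylpropanoid and flavonoid genes fell (39 of 67, 15 rising; 54 changed adjusted over the list alone; adjusted p = 0.023, and adjusted p = 0.063 with an estimated correlation). WRKY genes fell (41 of 70, 20 rising; 61 changed adjusted over the list alone; adjusted p = 0.015, and adjusted p = 0.063 with an estimated correlation). WRKY24 (Os01g0826400) was 3.93-fold lower, against the rise of WRKY62. NAC genes fell at 200 mM (33 of 61, 49 changed adjusted over the list alone; adjusted p = 0.031, and adjusted p = 0.18 with an estimated correlation) and at 50 mM (27 of 61, 38; adjusted p = 0.042, and adjusted p = 0.2 with an estimated correlation). At 50 mM heat shock proteins and chaperones also fell (93 of 198, 51 rising; 147 changed adjusted over the list alone; adjusted p = 0.0072, and adjusted p = 0.046 with an estimated correlation), as did antioxidant enzymes (65 of 134, 101 changed adjusted over the list alone; adjusted p = 0.04, and adjusted p = 0.11 with an estimated correlation). Ascorbate peroxidase (Os07g0694700), which removes hydrogen peroxide, was 4.96-fold lower. The late embryogenesis and abscisic acid list fell at 50 mM (23 of 47, 35 changed adjusted over the list alone; adjusted p = 0.034, and adjusted p = 0.19 with an estimated correlation). One of its falling members, Os01g0848700 (1.86-fold lower), is a Ras-related Rab11C gene caught by name, and Rab11 proteins act in vesicle traffic.

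Single genes of lists that did not pass as lists in AHX shoots also changed. A gene described as cytochrome P450 90C1 (Os02g0703600) was 7.65-fold lower at 200 mM (SE 0.031 on the log2 scale). NADH-glutamate synthase 2 (Os05g0555600), which assimilates nitrogen, was 4.74-fold lower. Trehalose-6-phosphate phosphatase (Os02g0661100) was 4.73-fold and a Bowman-Birk trypsin inhibitor (Os01g0124000) 4.42-fold lower. A plasma membrane aquaporin (Os09g0541000) was 4.38-fold lower and the starch-degrading alpha-amylase 3D (Os08g0473900) 4.27-fold lower. The response regulator Os02g0557800, of a family that acts in cytokinin signalling, was 2.78-fold higher, and adenine phosphoribosyltransferase 2 (Os02g0613900), which salvages purines, 2.03-fold higher. Nicotianamine synthase 1 (Os03g0307300) was at least 2.04-fold lower, its treated channel not being well above background. In all, 17660 of 24934 genes tested passed at 200 mM, 9052 higher and 8608 lower, and 721 of them changed by at least 2-fold, 209 higher and 512 lower. At 50 mM 14895 of 24933 passed, 7433 higher and 7462 lower, and 48 were at least 2-fold higher against 366 lower. The scanner's processed signals gave 1535 and 812 genes past 2-fold, of which 53.9% and 73.6% were lower, against 71% and 88.4% here, and raised the share of higher calls at 50 mM from 49.9% to 61.4%. Without the replicate block 10923 and 7289 genes passed.

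AOH was compared with the same kind of control in shoots. With 200 mM AOH an RCC1 domain gene (Os01g0846800) was 15.5-fold higher (log2 3.95 ± 0.069 SE, n = 2), the chlorophyll a-b binding protein 2 gene Os01g0600900 14.9-fold higher (log2 3.89 ± 0.036) and a MYB gene (Os06g0728700), of a transcription factor family, 14.8-fold higher. A B-box zinc finger gene (Os08g0249000) rose 13.8-fold, a CONSTANS-like gene (Os10g0560400), of a family that includes regulators of flowering time, 13.7-fold, and the MtN3 gene Os01g0700100 11.1-fold. The ENOD93 gene Os06g0142300 was 20-fold lower (log2 -4.32 ± 0.034), a kelch domain gene (Os06g0594400) 16.8-fold lower and the class III peroxidase gene Os02g0240300 14.2-fold lower. The CRT/DRE-type factor RCBF3 (Os09g0522200) fell by 3.78 on the log2 scale, or 13.7-fold, a thaumatin family gene (Os12g0569500) was 12.9-fold lower, and a KI domain interacting kinase gene (Os07g0628900) 12.6-fold lower. At 50 mM the increases were led by the MtN3 gene (12.5-fold), the MYB gene (log2 3.42), SIGE (10.4-fold) and a Dof zinc finger gene (Os01g0264000, 9.02-fold). The decreases were led by the kelch gene (24.5-fold), ENOD93 (15.4-fold), RCBF3 (14.7-fold) and the small heat shock protein Os02g0758000 (13.1-fold). The adjusted p of these genes lay between 2.7e-14 and 2.1e-12, and the SE of the genes named for AOH in shoots was at most 0.141 on the log2 scale.

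Cell wall genes rose with AOH in shoots: 97 of 155 at 50 mM against 29 that fell (127 changed adjusted over the list alone; median 0.25, adjusted p = 8.2e-05, and adjusted p = 0.096 with an estimated correlation). At 200 mM 93 rose and 36 fell (131; adjusted p = 0.0022, and adjusted p = 0.12 with an estimated correlation). EXPA2 was 6.84-fold higher at 200 mM and the pectin-degrading polygalacturonase PG2 (Os01g0636500) 4.19-fold higher at 50 mM, while a xyloglucan endotransglycosylase (Os06g0696600) was 4.94-fold lower at 200 mM. UDP-glycosyltransferases rose, 80 of 129 at 200 mM against 30 that fell (112 changed adjusted over the list alone; adjusted p = 0.0012, and adjusted p = 0.12 with an estimated correlation). At 50 mM 78 rose and 33 fell (114; adjusted p = 0.015, and adjusted p = 0.1 with an estimated correlation). Cytokinin genes rose at 200 mM, 10 of 12 against 2 that fell (12 changed adjusted over the list alone; median 0.69, adjusted p = 0.025, and adjusted p = 0.27 with an estimated correlation), among them the response regulators Os02g0557800 (3.5-fold), Os04g0673300 (2.43-fold) and Os11g0143300 (2.06-fold). At 50 mM class III peroxidases rose, 53 of 95 against 21 that fell (74 changed adjusted over the list alone; adjusted p = 0.031, and adjusted p = 0.33 with an estimated correlation).

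Bowman-Birk inhibitors, which block digestive proteases, fell with AOH in shoots: 7 of 9 at 200 mM, 1 rising (8 changed adjusted over the list alone; median -1.01, adjusted p = 0.015, and adjusted p = 0.12 with an estimated correlation). At 50 mM 7 of 9 fell (7; median -0.76, adjusted p = 0.015, and adjusted p = 0.096 with an estimated correlation). Os01g0123900 was 6.45-fold lower at 200 mM and Os03g0823400 4.52-fold lower at 50 mM. Ethylene genes fell, 25 of 39 at 200 mM (35 changed adjusted over the list alone; adjusted p = 0.015, and adjusted p = 0.12 with an estimated correlation). At 50 mM 24 of 39 fell (35; adjusted p = 0.03, and adjusted p = 0.096 with an estimated correlation), led by the ethylene-responsive factors Os02g0654700 (8.7-fold lower) and Os09g0287000 (5.21-fold lower). WRKY genes fell, 39 of 70 at 200 mM (55 changed adjusted over the list alone; adjusted p = 0.02, and adjusted p = 0.12 with an estimated correlation). At 50 mM 38 of 70 fell (55; adjusted p = 0.019, and adjusted p = 0.096 with an estimated correlation), led by WRKY28 (Os06g0649000, 5.16-fold lower at 50 mM) and WRKY10 (Os01g0186000, 4.56-fold lower at 200 mM). Jasmonate genes fell at 50 mM, 26 of 38 (35 changed adjusted over the list alone; adjusted p = 0.0032, and adjusted p = 0.1 with an estimated correlation). The tify gene Os10g0391400 was 12-fold lower at 50 mM. Antioxidant enzymes fell at 50 mM, 80 of 134 against 35 that rose (119 changed adjusted over the list alone; adjusted p = 0.0045, and adjusted p = 0.096 with an estimated correlation). Cytosolic ribosomal protein genes fell slightly at 200 mM, 81 of 145 against 21 that rose (102 changed adjusted over the list alone; median -0.08, adjusted p = 0.018, and adjusted p = 0.37 with an estimated correlation).

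Photosynthesis genes went both ways with AOH in shoots and did not pass as a list: at 200 mM 24 of 52 rose and 22 fell (47 changed adjusted over the list alone; median 0.03, adjusted p = 0.63). The type I chlorophyll a/b-binding protein gene Os01g0720500 was 8.73-fold higher. Other changed genes were the aquaporin Os09g0541000 (9.66-fold lower at 200 mM) and NADH-glutamate synthase 2 (Os05g0555600, 11.6-fold lower at 50 mM). In purine metabolism the list did not pass at 200 mM (11 of 32 rose, 16 fell and 5 did not pass; 27 changed adjusted over the list alone; median -0.1, adjusted p = 0.33), but its members allantoin permease (Os12g0503000) and amidophosphoribosyltransferase (Os05g0430800), the entry enzyme of purine synthesis, were 4.43-fold and 2.97-fold lower. GSTF14 and GSTF15 were 4.92-fold and 4.55-fold higher, with 28 of 51 glutathione S-transferases rising and 16 falling (44 changed adjusted over the list alone; adjusted p = 0.15). With 200 mM AOH 19471 of 24933 genes passed, 9678 higher and 9793 lower, and 796 were at least 2-fold higher against 873 lower. With 50 mM 19037 of 24934 passed, 9646 higher and 9391 lower, and 700 were at least 2-fold higher against 762 lower. The scanner's processed signals gave 3063 and 2789 genes past 2-fold.

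**Figure D1:**
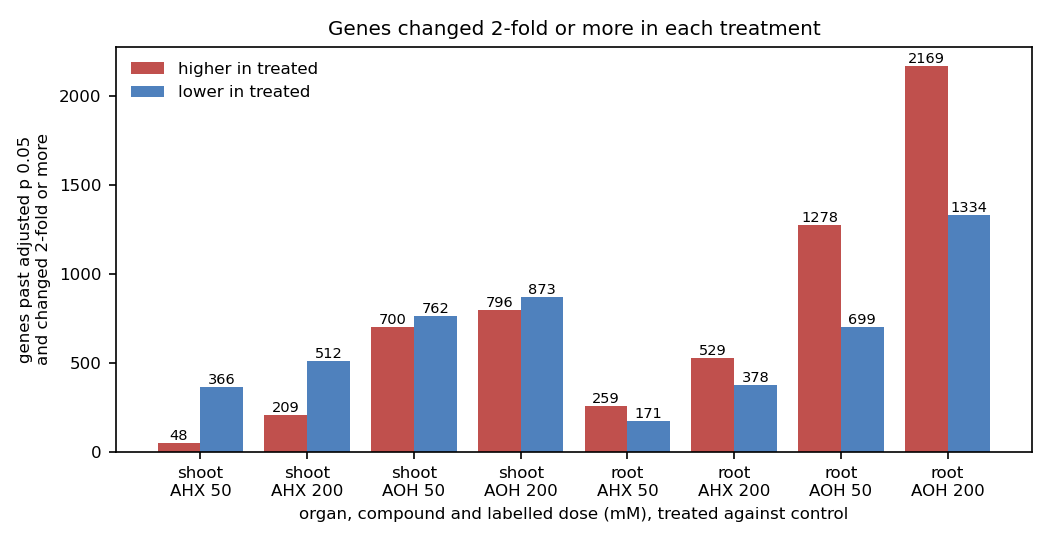
Number of genes past the limma threshold with a change of at least 2-fold, higher (likely direction) or lower than the control on the same arrays, per organ, compound and dose in mM, 2 arrays per group. The counts run from 48 higher genes with 50 mM AHX in shoots to 2169 with 200 mM AOH in roots.

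In roots, 200 mM AHX raised the chalcone synthase C2 gene (Os11g0530600), whose enzyme opens flavonoid synthesis, by 23.8-fold (log2 4.57 ± 0.045 SE, n = 2). Several glutathione S-transferases rose with it: GST6 (Os09g0367700) 17.5-fold (log2 4.13 ± 0.041), the tau-class GST 4 (Os10g0528300) 17.4-fold and GSTU35 (Os10g0368100) 10.8-fold. A ubiquitin gene (Os09g0483400) was higher by 3.42 on the log2 scale and the MYB gene Os06g0728700 9.74-fold higher. A gene with a Rossmann-like fold (Os05g0355400) was 17.2-fold lower (log2 -4.11 ± 0.045), a gene described as similar to a planthopper-induced resistance protein (Os02g0818000) 12-fold lower, an integrase domain gene (Os07g0434200) 9.52-fold lower and a RING/FYVE/PHD zinc finger gene (Os01g0212700) 7.61-fold lower. A wound-induced protein gene (Os04g0635500) and a universal stress protein gene (Os07g0673400) were 7.58-fold and 7.44-fold lower. At 50 mM chalcone synthase (13.8-fold), GST6 (10.2-fold), GST 4 (9.82-fold) and cinnamoyl-CoA reductase (Os02g0811800, 7.41-fold), a lignin enzyme, led the increases. Os02g0818000 led the decreases at 7.75-fold. The adjusted p of these genes lay between 1.4e-13 and 6.2e-11, and the SE of the genes named for AHX in roots was at most 0.092 on the log2 scale.

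Glutathione S-transferases rose as a group with AHX in roots: 38 of 56 at 200 mM against 11 that fell (49 changed adjusted over the list alone; median 0.39, with 0.34 and 0.37 within the slide of each replicate, adjusted p = 3.9e-05, and adjusted p = 0.11 with an estimated correlation). At 50 mM 36 rose and 12 fell (48; median 0.3, with 0.36 and 0.27 within slides, adjusted p = 3e-05, and adjusted p = 0.11 with an estimated correlation). Class III peroxidases, which act on cell walls, rose in 61 of 104 at 200 mM against 27 that fell (89 changed adjusted over the list alone; median 0.3, with 0.31 and 0.26 within slides, adjusted p = 4e-04, and adjusted p = 0.15 with an estimated correlation). At 50 mM 60 rose and 22 fell (82; adjusted p = 3e-05, and adjusted p = 0.12 with an estimated correlation). Os06g0681600 was 6.06-fold higher and peroxidase 27 (Os07g0104100) 5.39-fold higher at 200 mM. Cell wall genes rose, 90 of 176 at 200 mM against 44 that fell (134 changed adjusted over the list alone; adjusted p = 0.006, and adjusted p = 0.19 with an estimated correlation). At 50 mM 95 rose and 36 fell (131; adjusted p = 4e-04, and adjusted p = 0.12 with an estimated correlation). The expansin EXPA3 (Os05g0276500) was 6.1-fold higher at 200 mM. Cytosolic ribosomal protein genes rose, 105 of 145 at 200 mM against 12 that fell (118 changed adjusted over the list alone; median 0.14, adjusted p = 5.3e-06, and adjusted p = 0.15 with an estimated correlation). At 50 mM 96 rose and 11 fell (110; median 0.11, adjusted p = 7e-06, and adjusted p = 0.14 with an estimated correlation). UDP-glycosyltransferases passed at 50 mM, 61 of 136 rising and 32 falling (95 changed adjusted over the list alone; adjusted p = 0.048, and adjusted p = 0.19 with an estimated correlation).

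Photosynthesis genes fell with AHX in roots: 37 of 52 at 200 mM against 7 that rose (44 changed adjusted over the list alone; median -0.39, with -0.32 and -0.42 within slides, adjusted p = 5.3e-06, and adjusted p = 0.19 with an estimated correlation). At 50 mM 43 fell and 4 rose (48; median -0.51, with -0.52 and -0.58 within slides, adjusted p = 1.8e-12, and adjusted p = 0.11 with an estimated correlation). WRKY genes fell, 43 of 66 at 200 mM against 7 that rose (50 changed adjusted over the list alone; median -0.32, with -0.27 and -0.31 within slides, adjusted p = 5.3e-06, and adjusted p = 0.099 with an estimated correlation). At 50 mM 41 fell and 9 rose (50; adjusted p = 3.5e-05, and adjusted p = 0.11 with an estimated correlation), with WRKY76 (Os09g0417600) 2.63-fold and WRKY67 (Os05g0183100) 2.55-fold lower at 200 mM. Diterpenoid phytoalexin genes, which rose with AHX in shoots, fell in roots at 200 mM, 8 of 9 (also 8 adjusted over the list alone; median -0.81, with -0.67 and -0.95 within slides, adjusted p = 0.00049, and adjusted p = 0.099 with an estimated correlation). Among them were CYP99A1 (Os04g0178400, 3.65-fold) and syn-copalyl diphosphate synthase (Os04g0178300, 3.11-fold), the enzyme that starts momilactone synthesis. Bowman-Birk inhibitors fell at 200 mM, 5 of 6 (also 5 adjusted over the list alone; median -0.77, adjusted p = 0.0028, and adjusted p = 0.11 with an estimated correlation). Of these Os03g0661600 (1.81-fold lower) is an alpha-amylase/trypsin inhibitor. Ethylene genes fell, 27 of 42 at 200 mM (36 changed adjusted over the list alone; adjusted p = 0.0035, and adjusted p = 0.11 with an estimated correlation). At 50 mM 22 of 42 fell (36; adjusted p = 0.035, and adjusted p = 0.12 with an estimated correlation), although the ethylene-responsive factor Os06g0592500 was 3.6-fold higher at 200 mM. Nitrogen genes fell, 36 of 66 at 200 mM against 19 that rose (55 changed adjusted over the list alone; adjusted p = 0.018, and adjusted p = 0.15 with an estimated correlation). At 50 mM 36 fell and 14 rose (50; adjusted p = 0.0087, and adjusted p = 0.12 with an estimated correlation), while a high-affinity nitrate transporter (Os01g0704100) was 2.88-fold higher at 200 mM.

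The phenylpropanoid list did not pass in AHX roots (29 of 67 rose, 24 fell and 14 did not pass at 200 mM; 53 changed adjusted over the list alone; median 0.03, adjusted p = 0.46) although 10 members rose at least 2-fold, among them 4-coumarate-CoA ligase 1 (Os02g0697400, 9.08-fold, well above background in the control channel on 1 of 2 arrays) and a chalcone isomerase domain gene (Os12g0115700, 7.47-fold). The nicotianamine synthases NAS1 (Os03g0307300) and NAS2 (Os03g0307200), which make the metal chelator nicotianamine, were 4.19-fold and 4.43-fold lower. Heat shock factor 29 (Os01g0733200) was 4.65-fold lower, and the tonoplast aquaporin TIP2 (Os02g0658100) 4.3-fold higher. At 200 mM 17949 of 25087 genes passed, 9090 higher and 8859 lower, and 529 were at least 2-fold higher against 378 lower. At 50 mM 16247 of 25090 passed, 8381 higher and 7866 lower, and 259 were at least 2-fold higher against 171 lower. The scanner's processed signals gave 2100 and 1120 genes past 2-fold, and without the replicate block 11358 and 8690 genes passed.

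With 200 mM AOH in roots, an IAA-amino acid hydrolase gene (Os03g0836800), of a family that frees auxin from its conjugates, was 50.9-fold higher (log2 5.67 ± 0.056 SE, n = 2), cinnamoyl-CoA reductase (Os02g0811800) 24.8-fold higher and the tau-class GST 4 gene Os10g0528300 24.6-fold higher. A gene of the pollen Ole e 1 allergen and extensin kind (Os10g0546100) rose 24-fold, GST6 (Os09g0367700) 22.3-fold and the MYB gene Os06g0728700 21.2-fold. The nicotianamine synthases NAS1 (Os03g0307300) and NAS2 (Os03g0307200) were 44.3-fold lower (log2 -5.47 ± 0.048) and 35.4-fold lower (log2 -5.14 ± 0.031), and the Rossmann-like fold gene Os05g0355400 41.7-fold lower. Os02g0818000, described as similar to a planthopper-induced resistance protein, fell 25.5-fold, the light-regulated Lir1 gene (Os01g0102900) 22.6-fold, and an ankyrin repeat gene (Os09g0343200), well above background in the treated channel on 1 of 2 arrays, 17.4-fold. At 50 mM the IAA-amino acid hydrolase gene (23.2-fold), the MYB gene (17.7-fold), Os10g0546100 (14.6-fold) and the root-specific RCc2 gene (Os10g0551800, 12.9-fold) led the increases. Os05g0355400 (21.2-fold), Lir1 (11.6-fold), a universal stress protein (Os07g0673400, 11.5-fold) and Os02g0818000 (11.3-fold) led the decreases. The adjusted p of these genes lay between 4e-15 and 2.7e-13, and the SE of the genes named for AOH in roots was at most 0.114 on the log2 scale. In the array's genome build the probes for NAS2 and NAS1 lie side by side on chromosome 3, at 10975726 to 10975785 and 10977536 to 10977595. The probe of the hydrolase gene Os03g0836800 lies on the same chromosome at 36061659 to 36061718, and that of Os05g0355400 on chromosome 5 at 16889751 to 16889810.

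Class III peroxidases rose broadly with AOH in roots. At 200 mM 79 of 104 rose, 47 of them at least 2-fold, 20 fell and 5 did not pass (99 changed adjusted over the list alone; median 0.87, with 0.87 and 0.92 within the slide of each replicate, adjusted p = 2e-07, and adjusted p = 0.08 with an estimated correlation). At 50 mM 80 rose and 21 fell (101; median 0.73, with 0.65 and 0.74 within slides, adjusted p = 4.4e-08, and adjusted p = 0.096 with an estimated correlation). Os06g0681600 was 17.7-fold, Os01g0294700 14.2-fold and Os07g0676900 12.1-fold higher at 200 mM. Cell wall genes rose, 123 of 176 at 200 mM, 72 of them at least 2-fold, against 37 that fell (161 changed adjusted over the list alone; median 0.79, with 0.71 and 0.79 within slides, adjusted p = 9e-07, and adjusted p = 0.08 with an estimated correlation). At 50 mM 121 rose and 35 fell (157; median 0.52, adjusted p = 8.8e-08, and adjusted p = 0.096 with an estimated correlation). EXPA3 (Os05g0276500) was 14.6-fold higher and a cellulose synthase (Os10g0467800) 8.37-fold higher. Aquaporins, the water channels, rose in 13 of 17 at 200 mM against 3 that fell (16 changed adjusted over the list alone; median 1.02, with 1.4 and 0.59 within slides, adjusted p = 0.013, and adjusted p = 0.12 with an estimated correlation). At 50 mM 11 rose and 3 fell (14; median 1.06, adjusted p = 0.014, and adjusted p = 0.11 with an estimated correlation). TIP2 (Os02g0658100) was 15.1-fold higher at 200 mM and a NOD26-like channel (Os06g0228200) 6.92-fold higher at 50 mM. Phenylpropanoid and flavonoid genes rose, 47 of 67 at 200 mM against 17 that fell (64 changed adjusted over the list alone; median 0.46, adjusted p = 0.0069, and adjusted p = 0.08 with an estimated correlation). At 50 mM 40 rose and 19 fell (60; adjusted p = 0.041, and adjusted p = 0.11 with an estimated correlation). Chalcone synthase (Os11g0530600) was 18.1-fold higher and a caffeoyl-CoA O-methyltransferase (Os08g0498400) 5.13-fold lower at 200 mM. UDP-glycosyltransferases rose at 200 mM, 80 of 136 against 40 that fell (120 changed adjusted over the list alone; adjusted p = 0.022, and adjusted p = 0.19 with an estimated correlation). Of its leading members Os12g0443500 (5.48-fold) is a UDP-glucose 6-dehydrogenase, which makes a wall polysaccharide precursor. Cytosolic ribosomal protein genes rose, 106 of 145 at 200 mM against 18 that fell (124 changed adjusted over the list alone; median 0.23, with 0.17 and 0.27 within slides, adjusted p = 1.7e-05, and adjusted p = 0.19 with an estimated correlation). At 50 mM 113 rose and 13 fell (127; median 0.17, adjusted p = 2.1e-06, and adjusted p = 0.16 with an estimated correlation).

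Photosynthesis genes fell with AOH in roots, 41 of 52 at 200 mM, 30 of them at least 2-fold, against 10 that rose (51 changed adjusted over the list alone; median -1.25, with -1.32 and -1.19 within slides, adjusted p = 8.8e-07, and adjusted p = 0.19 with an estimated correlation). At 50 mM 44 fell and 6 rose (50; median -1.11, with -0.94 and -1.02 within slides, adjusted p = 9e-10, and adjusted p = 0.12 with an estimated correlation). The Rubisco small subunit genes Os12g0292400, Os12g0274700 and Os12g0291100 were 7.54-fold, 7.04-fold and 6.37-fold lower at 200 mM. WRKY genes fell, 45 of 66 at 200 mM against 9 that rose (54 changed adjusted over the list alone; median -0.48, with -0.5 and -0.46 within slides, adjusted p = 4.3e-05, and adjusted p = 0.08 with an estimated correlation). At 50 mM 44 fell and 11 rose (55; adjusted p = 9.4e-06, and adjusted p = 0.096 with an estimated correlation). WRKY62 (Os09g0417800) was 3.49-fold lower at 50 mM. Nitrogen genes fell at 200 mM, 40 of 66 against 17 that rose (57 changed adjusted over the list alone; adjusted p = 0.0097, and adjusted p = 0.14 with an estimated correlation), among them an ammonium transporter (Os02g0620600, 4.2-fold lower) and Os03g0291500 (7.28-fold lower).

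Other lists held large changes of single members without passing at 200 mM AOH in roots. In the iron list 5 of 14 rose and 8 fell (13 changed adjusted over the list alone; median -0.16, adjusted p = 0.41), the fall of NAS1 and NAS2 among them. Of glutathione S-transferases 29 of 56 rose, 17 at least 2-fold, and 18 fell (47 changed adjusted over the list alone; median 0.15, adjusted p = 0.2). Auxin genes rose in 34 of 57 and fell in 20 (54 changed adjusted over the list alone; adjusted p = 0.42). An auxin-induced protein gene (Os09g0545300) was 6.42-fold lower. Phosphate starvation genes rose in 22 of 36 and fell in 9 (31 changed adjusted over the list alone; adjusted p = 0.15). Sugar genes rose in 49 of 104 and fell in 39 (88; adjusted p = 0.7) and ABC and MATE transporters rose in 31 of 98 and fell in 45 (76; adjusted p = 0.46). Heat shock and chaperone genes rose in 100 of 199 and fell in 81 (182; adjusted p = 0.62), heat shock factor 29 (Os01g0733200) being 15.5-fold lower. Cytochromes P450 rose in 81 of 192 and fell in 94 (175 changed adjusted over the list alone; median -0.07 and mean 0.03, adjusted p = 0.63). Pathogenesis-related genes rose in 49 of 111 and fell in 54 (103; median -0.03 and mean 0.06, adjusted p = 0.7). The histone and cell cycle list, which also catches cyclin-like F-box genes such as Os09g0324400 (5.52-fold higher), rose in 134 of 297 and fell in 121 (255 changed adjusted over the list alone; adjusted p = 0.7). Seed storage genes rose in 19 of 40 and fell in 15 (34 changed adjusted over the list alone; adjusted p = 0.41). Lipid transfer type members such as Os01g0914300 (5.61-fold higher) lead it beside the glutelin gene Os01g0607000 (4.24-fold higher). Among the 8 treatments, median, mean and test of a list differed in sign in 21 cases, and in 0 of them did the list pass. Cytochromes P450 made up 6 of these, and others were glutathione S-transferases with 50 mM AOH in roots (median -0.03, mean 0.19) and aquaporins with 200 mM AHX in shoots (median 0.06, mean -0.16). With 200 mM AOH 21082 of 25090 root genes passed, 10703 higher and 10379 lower, and 2169 were at least 2-fold higher against 1334 lower. With 50 mM 19025 of 25089 passed, 9626 higher and 9399 lower, and 1278 were at least 2-fold higher against 699 lower. The scanner's processed signals gave 5511 and 3543 genes past 2-fold, and turned the balance of all calls to 9358 higher and 11309 lower at 200 mM and to 8511 and 10261 at 50 mM.

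**Figure D2:**
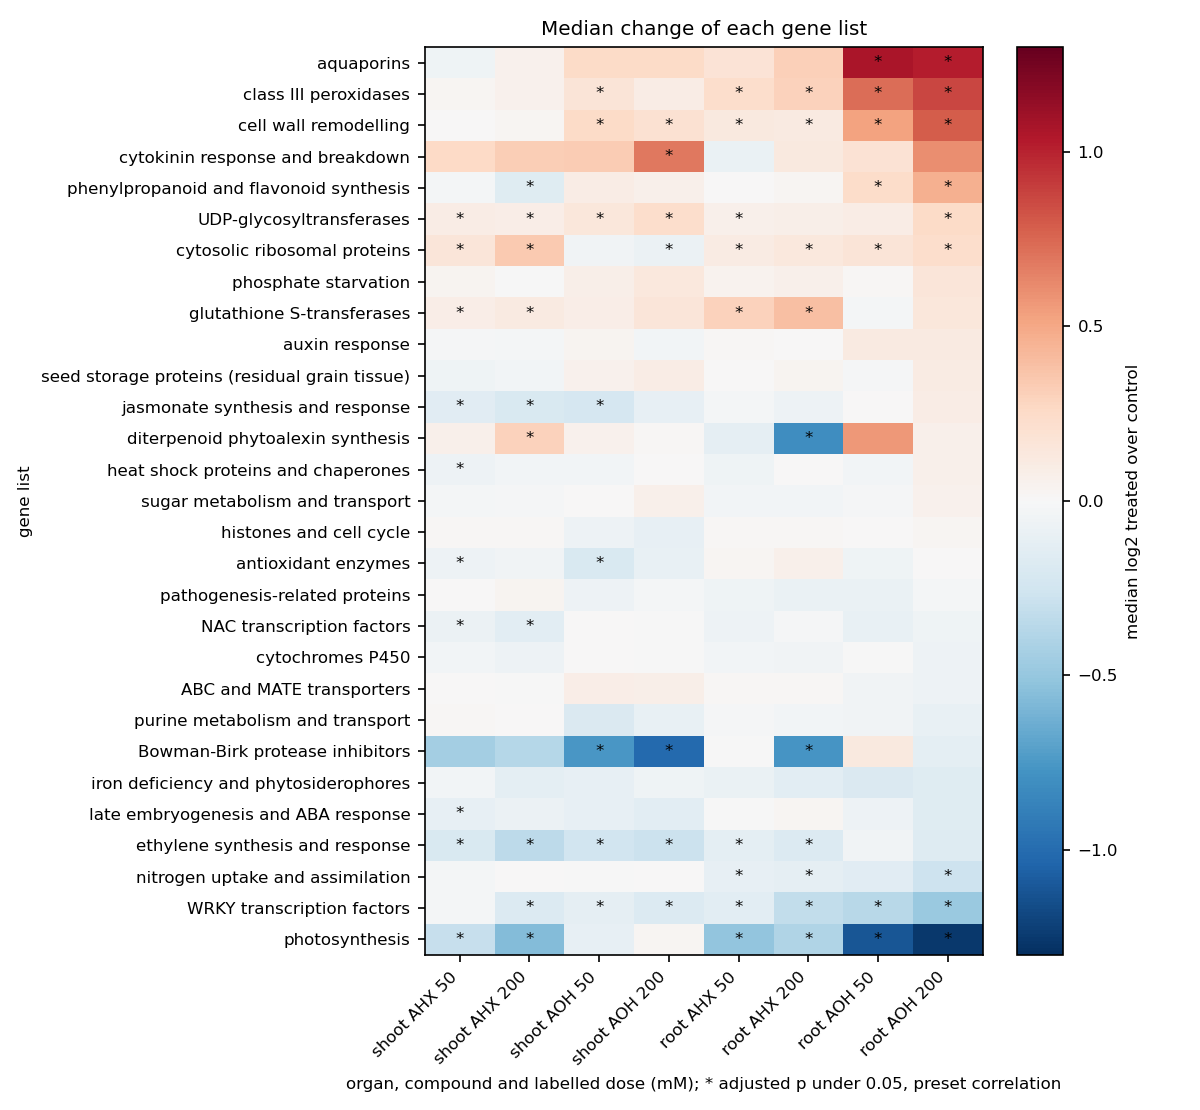
Median log2 change (likely direction) of each of the 29 gene lists in the 8 treatments, with dose in mM, from blue (lower than control) to red (higher); an asterisk marks an adjusted p under 0.05 at the preset correlation. With 200 mM AOH in roots aquaporins (1.02), peroxidases (0.87) and cell wall genes (0.79) are the reddest, and photosynthesis genes (-1.25) the bluest.

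**Figure D3:**
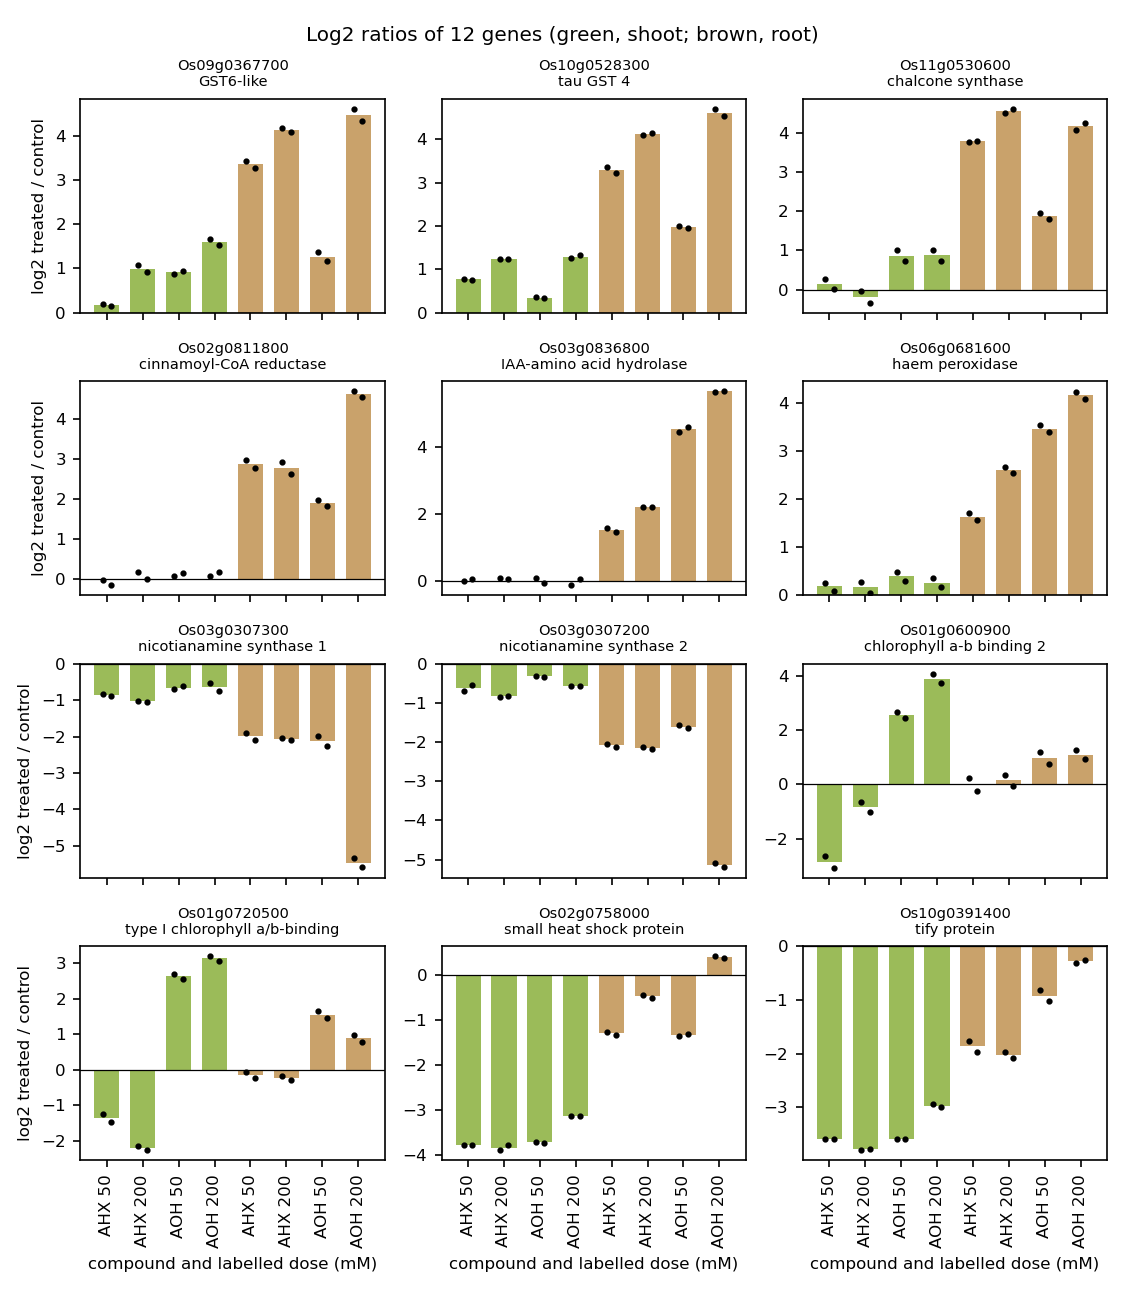
Log2 treated-over-control ratios (likely direction) of 12 genes, chosen after their values were seen, with shoots in green, roots in brown and dose in mM; bars are the means and points the 2 arrays of a group, and no bar is drawn where a gene was not tested. NAS1 and NAS2 reach -5.47 and -5.14 with 200 mM AOH in roots, and the IAA-amino acid hydrolase gene 5.67.

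The 2 doses were compared within each organ and compound. In shoots with AHX the chlorophyll a-b binding protein gene Os01g0600900 was higher at 200 than at 50 mM by 4.04-fold (log2 2.01 ± 0.051 SE, n = 2 against 2) and a light-harvesting complex I type gene (Os08g0435900) by 2.96-fold, beside the early light-induced genes Os01g0246400 (3.78-fold) and Os07g0178800 (2.96-fold). Another chlorophyll-binding gene, Os01g0720500, was lower (log2 -0.85), and the photosynthesis list did not pass (16 of 52 rose and 14 fell; 32 changed adjusted over the list alone; median -0.04 and mean 0.09, adjusted p = 0.98). With AOH in shoots Os09g0346500 was higher by 5.1-fold (log2 2.35 ± 0.052) and Os03g0592500 by 3.04-fold, beside the RCC1 domain gene (Os01g0846800, 3.96-fold) and a sodium/sulphate symporter (Os08g0503700, 3.12-fold). The peroxidase gene Os02g0240300 was lower at the higher dose of either compound (2.16-fold with AHX and 2.33-fold with AOH), as was the thaumatin gene Os12g0569500 (2.36-fold and 2.09-fold). A lipid transfer protein (Os10g0504900, 2.93-fold) and the aquaporin Os09g0541000 (2.55-fold) were lower with AHX. In roots the largest dose differences with AOH were those of NAS2 (Os03g0307200, 11.7-fold lower at 200 mM, log2 -3.55 ± 0.043), NAS1 (Os03g0307300, 10.2-fold lower) and GST6 (Os09g0367700, 9.3-fold higher, log2 3.22 ± 0.058). The elongation factor EF-2 gene Os01g0723000 (7.33-fold), the heat shock protein gene Os03g0267000 (6.64-fold) and cinnamoyl-CoA reductase (Os02g0811800, 6.61-fold) were also higher. A BURP domain gene (Os05g0217700, 7.13-fold) and a type 1 metallothionein (Os12g0571000, 6.24-fold), which binds metals, were lower. With AHX in roots an isopenicillin N synthase family gene (Os05g0560900, 4.38-fold, SE 0.245 on the log2 scale), a Dof3 gene (Os07g0685000, 3.42-fold) and Os08g0435900 (3.41-fold) were higher. A nodulin-like gene (Os01g0117900) was 5.54-fold lower, Os10g0320400 4.2-fold lower by a probe whose 1 companion probe went the other way, and a PR1a gene (Os07g0129300) 3.49-fold lower.

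Among the lists, cytosolic ribosomal protein genes rose with AHX dose in shoots, 109 of 145 against 1 that fell (121 changed adjusted over the list alone; median 0.18, adjusted p = 2.6e-17, and adjusted p = 0.035 with an estimated correlation). Ethylene, phenylpropanoid and WRKY genes fell with AHX dose there (19 of 39, 27 of 67 and 25 of 70; 28, 38 and 33 changed adjusted over the list alone; adjusted p = 0.00045, 0.00037 and 0.0085, and adjusted p = 0.035, 0.035 and 0.044 with an estimated correlation). With AOH dose in shoots heat shock and chaperone genes rose, 60 of 198 against 21 (82 changed adjusted over the list alone; adjusted p = 0.0019, and adjusted p = 0.022 with an estimated correlation). UDP-glycosyltransferase, phosphate starvation and antioxidant genes rose too, 47 of 129, 16 of 35 and 53 of 134 against 14, 2 and 17 (68, 20 and 80; adjusted p = 0.0012, 0.0022 and 0.0032, and adjusted p = 0.046, 0.037 and 0.037 with an estimated correlation). Histone and cell cycle genes fell, 72 of 283 against 25, and auxin genes, 23 of 67 against 5 (97 and 29; adjusted p = 0.0065 and 0.0038, and adjusted p = 0.037 with an estimated correlation for each). Photosynthesis genes rose, 24 of 52 against 8 (34; median 0.14, adjusted p = 3.4e-05, and adjusted p = 0.22 with an estimated correlation). With AHX dose in roots diterpenoid phytoalexin genes fell, 7 of 9 (8 changed adjusted over the list alone; median -0.73, adjusted p = 2.3e-06, and adjusted p = 0.025 with an estimated correlation). WRKY genes fell, 27 of 66 with 0 rising, and Bowman-Birk inhibitors, 5 of 6 with 1 rising (33 and 6; medians -0.12 and -0.7, adjusted p = 4.3e-06 and 3.6e-05, and adjusted p = 0.034 with an estimated correlation for each). Heat shock and chaperone genes rose, 53 of 199 against 13 (74; adjusted p = 0.0088, and adjusted p = 0.025 with an estimated correlation). With AOH dose in roots glutathione S-transferases rose, 32 of 56 against 8 (41 changed adjusted over the list alone; median 0.35, adjusted p = 0.00015, and adjusted p = 0.11 with an estimated correlation). Photosynthesis genes fell, 33 of 52 against 14 (47; median -0.36, adjusted p = 0.0021, and adjusted p = 0.27 with an estimated correlation). The dose changed 8816 genes with AHX and 9159 with AOH in shoots, 35 and 52 of them at least 2-fold, and 5874 and 14486 in roots, 128 and 464 of them at least 2-fold. Without the replicate block these were 1485, 1830, 1471 and 6516 genes, with the thaumatin gene (either compound) and Os03g0592500 no longer past the threshold. With median centring they were 4143, 4501 and 2934 for the first 3. Leaving out replicate 1 of 50 or of 200 mM AHX in shoots gave 5503 and 5550, replicate 1 of 50 or 2 of 200 mM AOH in shoots 6104 and 5997, and replicate 2 of 50 mM AHX in roots 3789. Processed signals gave 210, 240, 382 and 1168 genes past 2-fold and moved their lower share from 25% to 49.2% for AOH in shoots and from 35.1% to 46% for AOH in roots.

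AOH and AHX, which differ by the oxo group at carbon 8, were compared at matched dose. In shoots 4 chlorophyll-binding genes were higher with AOH than with AHX, Os01g0600900 by 41.8-fold at 50 mM (log2 5.39 ± 0.051 SE, n = 2 against 2) and 26.5-fold at 200 mM, Os01g0720500 by 15.7-fold and 40-fold, Os08g0435900 by 24.4-fold and 21-fold and Os03g0592500 by 15-fold and 25.6-fold. A polygalacturonase subunit gene (Os10g0409400) was lower with AOH, by 5.38-fold and 4.91-fold. So were, at 50 mM, a response regulator (Os01g0971800, 5.66-fold), Lir1 (Os01g0102900, 5.24-fold) and a DnaJ chaperone (Os04g0675400, 5.07-fold). At 200 mM a UspA domain gene (Os01g0303800, 3.98-fold), the peroxidase gene Os02g0240300 (3.95-fold) and a family 18 glycoside hydrolase (Os05g0247100, 3.83-fold) were lower. In roots at 200 mM the IAA-amino acid hydrolase gene (Os03g0836800) was 10.9-fold higher with AOH than with AHX (log2 3.45 ± 0.079), an aldo/keto reductase (Os10g0113100) 8.71-fold, a peroxidase (Os03g0234900) 6.49-fold and Os10g0546100 6.36-fold higher. NAS1 (10.6-fold, log2 -3.4 ± 0.068) and NAS2 (7.98-fold, log2 -3 ± 0.043) were lower with AOH, as were a terpenoid synthase gene (Os03g0347900) and a ferredoxin-type gene (Os07g0489800), each by 7.15-fold. At 50 mM in roots the GDSL lipase Os01g0216000 (12.8-fold), an isoflavone reductase type gene (Os01g0106400, 8.92-fold), the hydrolase gene (8.08-fold) and the BURP gene Os05g0217700 (7.4-fold) were higher with AOH. The nodulin-like Os01g0117900 (6.81-fold), Lir1 (4.43-fold) and the tau-class GST 3 (Os10g0527400, 4.34-fold) were lower.

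Cytosolic ribosomal protein genes were lower with AOH than with AHX in shoots, 143 of 145 at 200 mM (143 adjusted over the list alone; median -0.43, adjusted p = 2.1e-27, and adjusted p = 0.033 with an estimated correlation) and 122 of 145 at 50 mM (127; median -0.22, adjusted p = 1.6e-13, and adjusted p = 0.077 with an estimated correlation). Histone and cell cycle genes were lower at 200 mM, 146 of 283 against 43 (190 differed adjusted over the list alone; adjusted p = 0.0013, and adjusted p = 0.033 with an estimated correlation). Photosynthesis genes were higher with AOH in shoots, 33 of 52 at 200 mM against 10 (43 differed adjusted over the list alone; median 0.31, adjusted p = 2.8e-06, and adjusted p = 0.16 with an estimated correlation). They were lower in roots, 39 of 52 against 11 (50; median -0.97, with -1.02 and -0.88 within slides, adjusted p = 6.9e-08, and adjusted p = 0.18 with an estimated correlation). In roots at 200 mM class III peroxidases were higher with AOH, 78 of 104 against 15 (93 differed adjusted over the list alone; median 0.68, with 0.66 and 0.7 within slides, adjusted p = 1.6e-09, and adjusted p = 0.041 with an estimated correlation). Cell wall genes were higher too, 123 of 176 against 21 (144; median 0.57, with 0.52 and 0.58 within slides, adjusted p = 4.1e-10, and adjusted p = 0.041 with an estimated correlation). Aquaporins (14 of 17, 16 adjusted over the list alone; median 0.54, with 0.6 and 0.46 within slides), jasmonate genes (27 of 37, 31; median 0.35, with 0.29 and 0.42) and diterpenoid phytoalexin genes (8 of 9, 8; median 1, with 0.84 and 1.11) were also higher (adjusted p = 0.00099, 1e-04 and 2e-04, and adjusted p = 0.041 with an estimated correlation for each). At 50 mM in roots glutathione S-transferases were lower with AOH, 31 of 56 against 14 (46 differed adjusted over the list alone; median -0.18, adjusted p = 0.0015, and adjusted p = 0.16 with an estimated correlation). At 200 mM they did not pass as a list (median -0.04, adjusted p = 0.58).

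Some genes responded nearly alike to the compounds. Of genes changed at least 2-fold by either, the 95% interval of the difference lay within 0.5 log2 units of 0 for 256 of 1554 (16.5%) in shoots at 50 mM, 464 of 1848 (25.1%) in shoots at 200 mM, 154 of 2103 (7.3%) in roots at 50 mM and 402 of 3656 (11%) in roots at 200 mM. Examples, chosen after their values were seen, are the small heat shock protein Os02g0758000 in shoots at 50 mM (AOH minus AHX 0.07, interval -0.03 to 0.17), the tify gene Os10g0391400 there (0.01, interval -0.12 to 0.13), and the ubiquitin gene Os09g0483400 in roots at 200 mM (-0.06, interval -0.17 to 0.04). Changes across all genes correlated at 0.74 in shoots and 0.8 in roots at 200 mM (covariance 0.156 and 0.256) and at 0.67 and 0.72 at 50 mM (0.109 and 0.13). Unchanged groups simulated against a shared control gave 0.49 to 0.51, with covariances of 0.00075 to 0.00079. At 200 mM 461 root genes were at least 2-fold higher with both compounds and 292 lower with both (independent lists would share 45.7 and 20.1), and 159 and 372 shoot genes (6.7 and 17.9). The control channels cannot be split, so part of the excess may come from shared controls. AOH and AHX differed in 15322 and 15291 shoot genes at 50 and 200 mM, 572 and 477 at least 2-fold, and in 13812 and 16458 root genes, 861 and 1456 at least 2-fold. In shoots each compound was hybridised on a slide of its own, so compound and slide cannot be told apart there beyond the control on each array. Without the replicate block 7796, 7534, 6885 and 9482 genes differed. Processed signals gave 1260, 1122, 1788 and 2694 genes past 2-fold, and moved the lower share in shoots at 200 mM from 26.8% to 39.5%.

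**Figure D4:**
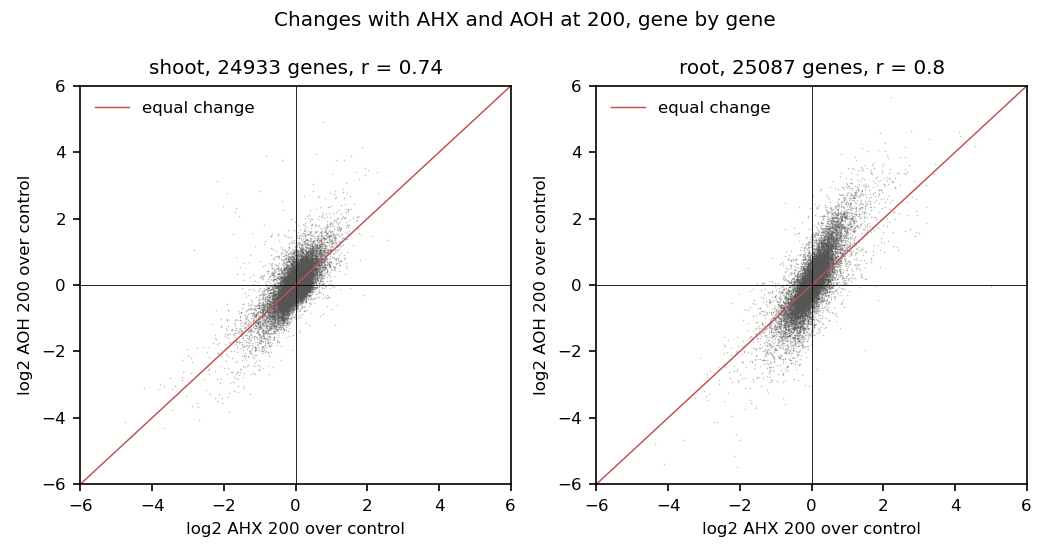
Log2 change of each gene (likely direction) with 200 mM AHX (horizontal) and 200 mM AOH (vertical) against control, in shoots (24933 genes) and roots (25087 genes), 1 point per gene; the red line marks equal change. The correlation across genes is 0.74 in shoots and 0.8 in roots.

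The response to each compound at 200 mM was compared between root and shoot, by the difference of their log2 changes. With AHX the change of the chalcone synthase gene (Os11g0530600) lay 4.75 log2 units higher in roots than in shoots (SE 0.064), that of a xyloglucan endotransglycosylase (Os06g0696600), which remodels cell walls, 3.75, that of the small heat shock protein Os02g0758000 3.35 and that of the GOS9 gene Os03g0399900 3.34 units higher. The BURP gene Os05g0217700 lay lower in roots (-4.19 ± 0.053), as did WRKY62 (Os09g0417800, -3.15), the cation transporter HKT1 (Os06g0701700, -3) and a ZMK2-type potassium channel (Os05g0428700, -2.97). With AOH the aldo/keto reductase Os10g0113100 (5.09 ± 0.049), a P7-type peroxidase (Os06g0547400, 4.7), Os06g0696600 (4.34) and an annexin (Os05g0382600, 4.11) lay higher in roots, and NAS1 (-4.84 ± 0.068), NAS2 (-4.58), the metallothionein Os12g0571000 (-3.91) and Os05g0217700 (-3.54) lay lower.

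Photosynthesis genes differed between the organs in opposite ways. With AOH 45 of 52 lay lower in roots than in shoots (51 differed adjusted over the list alone; median -1.56, adjusted p = 2.1e-13, and adjusted p = 0.096 with an estimated correlation). With AHX 27 lay higher and 11 lower (39; median 0.16, adjusted p = 0.012, and adjusted p = 0.44 with an estimated correlation). Cytosolic ribosomal protein genes lay higher in roots with AOH, 113 of 144 (122 differed adjusted over the list alone; median 0.33, adjusted p = 8.8e-08, and adjusted p = 0.12 with an estimated correlation). They lay lower with AHX, 110 of 144 (114; median -0.19, adjusted p = 1.5e-09, and adjusted p = 0.11 with an estimated correlation). Class III peroxidases lay higher in roots with AOH, 65 of 87 (79 differed adjusted over the list alone; median 0.81, adjusted p = 6.8e-07, and adjusted p = 0.096 with an estimated correlation). With AHX 45 of 87 did (63; adjusted p = 0.012, and adjusted p = 0.36 with an estimated correlation). Jasmonate genes lay higher in roots with AOH, 29 of 35 (34 differed adjusted over the list alone; median 0.65, adjusted p = 9.1e-05, and adjusted p = 0.096 with an estimated correlation). With AHX 23 of 35 did (29; adjusted p = 0.0019, and adjusted p = 0.11 with an estimated correlation). Diterpenoid phytoalexin genes lay lower in roots with AHX, 8 of 9 (8 adjusted over the list alone; median -1.29, adjusted p = 0.00012, and adjusted p = 0.051 with an estimated correlation). The responses differed for 15602 of 23809 genes with AHX, 1034 at least 2-fold, and for 18738 of 23811 with AOH, 2771 at least 2-fold. Shoot and root arrays were scanned on different days and lie on different slides, so organ, slide and scan day cannot be told apart. Without the replicate block 8305 genes differed with AHX. Processed signals gave 2008 and 4518 genes past 2-fold.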

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

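The tests of a transient response in the controls, of compression among brighter genes and of loess on processed signals were chosen only after the result was seen, as were the readings of the dim probe and normalization tests; the other tests given here were planned.

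Responses at 200 mM that differed between root and shoot, by a test of the difference itself, are given as root minus shoot on the log2 scale. With AHX 15602 genes differed. The named ones were Os11g0530600 (4.75), Os06g0696600 (3.75), Os02g0758000 (3.35), Os03g0399900 (3.34), Os05g0428700 (-2.97), Os06g0701700 (-3), Os09g0417800 (-3.15) and Os05g0217700 (-4.19). List medians were 0.3 for jasmonate, -1.29 for diterpenoid phytoalexin, 0.25 for phenylpropanoid, 0.21 for peroxidase, 0.16 for photosynthesis and -0.19 for ribosomal protein genes. With an estimated correlation 0 of these 6 lists passed in limma's camera, 4 having an unadjusted p under 0.05 (phenylpropanoid adjusted p = 0.0013, and adjusted p = 0.051 with an estimated correlation). With AOH 18738 genes differed, among them Os10g0113100 (5.09), Os06g0547400 (4.7), Os06g0696600 (4.34), Os05g0382600 (4.11), Os05g0217700 (-3.54), Os12g0571000 (-3.91), Os03g0307200 (-4.58) and Os03g0307300 (-4.84). Its list medians were -0.33 for nitrogen, 0.65 for jasmonate, 0.32 for phenylpropanoid, 0.81 for peroxidase, -1.56 for photosynthesis, 0.33 for ribosomal protein, 0.19 for histone and cell cycle and 0.36 for cell wall genes. With an estimated correlation 0 of these 8 passed, 7 having an unadjusted p under 0.05. For nitrogen, phenylpropanoid, histone and cell wall genes adjusted p = 0.013, 0.033, 0.037 and 0.013, and adjusted p = 0.16, 0.096, 0.096 and 0.18 with an estimated correlation.

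Photosynthesis genes fell in AOH roots while the list went both ways in AOH shoots. Shoot tissue in the control root RNA would lower every shoot gene, but the 200 other genes with the largest shoot excess had a median of 0.09 (quartiles -0.24 and 1.03; 97 rose and 70 fell) against -1.25 for the list. Dim probes are argued against, since the 48 members well above background on every root array had a median of -1.53. A root response to AOH and a difference in sampling hour stay open as hypotheses. Organ, slide and scan day were not told apart.

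With 200 mM AHX in shoots 71% of the genes changed 2-fold were lower. The scanner's processed signals gave 53.9%, first read as for normalization and then as against it. They change normalization and background handling together, so these cannot be told apart. Median centring alone left 68.2%. Loess on processed signals, already lowess scaled, gave 56.7% and decides nothing. Compression by the background offset, strongest on dim spots, stays open. Processed signals gave 67.4% above the median intensity (74.5% here) and 47.8% below it (65.5% here), where 1062 of their 1535 calls lay. Among probes well above background on all 8 shoot arrays 70.4% were lower, first read as against the offset. That filter removed only 18 of the 721 genes, so it was then taken to decide nothing about dim probes. A transient response of the control seedlings cannot be told apart from an effect common to the compounds, because the same lower genes had a median of -1.37 with 200 mM AOH, where 486 of 512 fell, and no untreated arrays stand beside the controls.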

How the results depend on the processing

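The dye term per slide in shoots and the fit without the 4 arrays of conflicting labels were chosen only after the data were seen; neither moved a count of genes by over 1.5 times or ended the call of any of the 249 and 301 named values they cover. The same holds for no background correction, Aquantile, no dim probe filter and the mean over probes, with all 487 named values. It also holds for the 469 of 487 still tested under the stricter filter, and for the arrays of one organ, with 471 of 487, a fit not run for the organ comparisons. Processed signals and the value table kept the counts past the threshold within 1.5 times and the calls of named genes, but raised each count of genes past 2-fold by 1.57 to 6.23 times. With the other orientation of replicate 2, 0 genes passed in each of the 18 comparisons with limma, where 40, 43, 42, 34, 24, 37, 31 and 57 genes in the treatments, 0, 0, 0 and 4 in the dose, 0, 0, 0 and 1 in the compound and 2 and 1 in the organ comparisons had an unadjusted p under 0.05. Of the 487 values of named genes 249 kept their direction and 238 turned it there, at log2 values of -0.48, -0.31, -0.26, -0.25, -0.23, -0.22, -0.21, -0.2, -0.19, -0.17, -0.16, -0.15, -0.13, -0.12, -0.11, -0.1, -0.09, -0.08, -0.07, -0.06, -0.05, -0.04, -0.03, -0.02, -0.01, 0, 0.01, 0.02, 0.03, 0.04, 0.05, 0.06, 0.07, 0.08, 0.09, 0.1, 0.11, 0.12, 0.13, 0.14, 0.15, 0.16, 0.17, 0.18, 0.19, 0.2, 0.21, 0.22, 0.23, 0.24, 0.25, 0.29, 0.3, 0.31, 0.35, 0.38, 0.39, 0.49 and 0.75, all without passing.

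Without the replicate block, which pairs arrays of one dye orientation and, in roots, of one slide, the counts were 7289 and 10923 genes for AHX at 50 and 200 mM in shoots, 8690 and 11358 in roots, 1485, 1830, 1471 and 6516 for dose (shoot AHX, shoot AOH, root AHX, root AOH), 7796 and 7534 for AOH against AHX in shoots, 6885 and 9482 in roots, and 8305 for root against shoot with AHX; the 5 other counts moved by less than 1.5 times, and 4 of 487 named values no longer passed. By construction the difference between the replicates of an organ then enters the spread. Median centring gave 4143, 4501 and 2934 genes for the first 3 dose comparisons, and the cause was not tested. With 1 array left out, which assumes that the lone array varies like the other groups, dose counts ran from 5503 (without replicate 1 of 50 mM; 5550 without replicate 1 of 200 mM) to 6307 for AHX in shoots. They ran from 5997 (without replicate 2 of 200 mM; 6104 without replicate 1 of 50 mM) to 6252 for AOH in shoots, and from 3789 (without replicate 2 of 50 mM) to 4654 for AHX in roots. Fewer arrays are the only change. With an estimated correlation the number of gene lists past the threshold was 1 and 2 for AHX in shoots, 0 for the 6 other treatments, 6 for AOH dose in shoots, 4 and 0 for AHX and AOH dose in roots, 0 and 2 for the compounds in shoots at 50 and 200 mM, 0 in roots at 50 mM, and 0 for either organ comparison. The number of arrays limits the precision; 80% to 83% of spots in Cy3 and 78.1% to 84% in Cy5 were well above background.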

Other observations

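The clock genes and their tests were chosen only after the result was seen. Several genes of the circadian clock changed with both compounds. The LHY-like gene Os08g0157600, a morning component of the clock, rose by 1.69 and 3.42 on the log2 scale with 200 mM AHX and AOH in shoots and by 2.13 and 2.67 in roots (SE 0.035 each, n = 2). GIGANTEA (Os01g0182600), which links the clock to flowering, fell by 1.14 and 1.9 in shoots and by 1.2 and 1.65 in roots. The FKF1-like gene Os11g0547000 fell by 1.34 and 1.86 in shoots and by 1.02 with either compound in roots, and the PRR73-like gene Os03g0284100 fell by 1.63 and 1.84 in shoots and by 1.22 and 1.18 in roots. The gene Os02g0148500, described as similar to TIMING OF CAB 1, moved by much less (-0.03 and -0.09 in shoots, where the first did not pass, and 0.22 and 0.21 in roots).

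A difference in sampling hour between treated and control seedlings may lie behind these changes. With 200 mM AOH the test asked for the LHY-like gene and the median of the 5 evening genes to go opposite ways by at least 0.5 in both organs. Roots met it (2.67 and -0.54), as different hours would give. In shoots the median was -0.25, with GIGANTEA and FKF1 falling while Os02g0148500 and Os11g0157600 stood at -0.09 and -0.08. A single hour for all treated seedlings and another for all controls would leave no difference between treated groups, yet in roots, where these share slides, 3 of the 8 clock genes differed between AOH and AHX at 50 mM by more than 0.5 beyond 2 SE (LHY-like 1.58, GIGANTEA -1.05 and PRR73-like -0.88), as did 2697 of all 25089 genes (in shoots, where compound and slide cannot be told apart, 5 of 8 at 50 mM and 3 of 8 at 200 mM). So did 3 of 8 between 200 and 50 mM AOH in roots (PRR73-like 1.45, Os07g0695100 0.83 and GIGANTEA 0.68). There 0 of 8 differed so between compounds at 200 mM (3993 of 25087 genes did), as a single hour would give. Between AHX doses 1 of 8 did. The readings of both tests, and the measure and prediction of the second, changed after the results were seen, so neither decides. With no sampling hours used, hours that differed by compound or dose cannot be told apart from a clock response.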
